A study of Mus musculus with 4 samples.

How the data were processed

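The series held 4 arrays with 2 colours each, 2 per time point, on which amplified RNA from cardiac endothelium of LPS-injected mice was compared with that of saline-injected mice at 4 h and at 24 h. Per the labels, LPS RNA carried Cy5 on replicate 1 of each time and Cy3 on replicate 2, which was named a dye reversal. The labels named no separate animals or extracts for the reversed array, so each pair was counted as 1 replicate, and LPS was tested against saline only in an alternative that took the arrays as separate samples. Whether the saline RNA of the 2 times was the same is not given in the sources used here.

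The deposited table held log2 ratios for 32448 spots per array, and the median of each array was 3e-07. The size of every value checked, those under 2 log2 units, was the log2 of a fold rounded to 0.01, within 2e-05 of a fold unit. Between 10.2% and 13.4% of the spots of an array had a ratio of exactly 1, taken as a log2 ratio within 1e-06 of 0, and whether these were measured or filled in is unknown. The steps from the scanner to the ratio, background correction, dye normalization and spot filters included, are not given in the sources used here. The table held no intensities, so weak spots could not be told from strong ones, and the number of arrays limits the precision.

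The direction of the deposited ratios was not stated. The rule fixed before the data were examined took the table as Cy5 over Cy3 if the 2 arrays of a time correlated below -0.3 over all spots, as already turned alike above 0.3, and in between as not settled, with sizes only to be given. The correlations were -0.056 at 4 h and -0.064 at 24 h, so this rule left the direction open. What follows departs from that rule, after the data were seen. Duplicate spots of an oligonucleotide correlated at only 0.19 to 0.32 within an array, so the test was repeated on oligonucleotides whose 2 spots lay within 0.5 log2 units of each other on both arrays, without ratios of exactly 1. Over these, the deposited values correlated at -0.37 at 4 h (5023 oligonucleotides) and -0.50 at 24 h (3668 oligonucleotides). Of those at least 2-fold from 1 on both arrays, 180 of 186 (96.8%) at 4 h and 435 of 458 (95.0%) at 24 h had opposite signs. The table was therefore taken as Cy5 over Cy3, and the sign of replicate 2 was turned. An excess of genes in the same direction over genes in opposite directions is thus not independent of this choice. The absolute direction, LPS over saline, rests on the dyes in the labels and is called likely. If the table held Cy3 over Cy5, every higher value would be lower and every lower value higher. The labels also listed LPS RNA as the second channel of all arrays. If the table was instead already turned alike, turning replicate 2 was wrong. Genes called in the same direction would then lie in opposite directions on the 2 arrays, as a gene's dye effect does.

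Adjacent spots held the same oligonucleotide, and the 2 spots were averaged, then the oligonucleotides of a gene, and each array was centred on its median over genes. Gene names came from the platform annotation, in which 24344 spots (75.0%) had 1 gene symbol, 98 had several and 8006 were not listed. Of the spots with 1 symbol, 24076 matched a gene of the RefSeq table of assembly GRCm38.p6 by gene identifier, which changed 0 symbols. No coordinates were used, since the files name no genome build. This gave 11138 genes, 958 of them with more than 1 oligonucleotide, and left 4052 oligonucleotides unnamed. Among called genes with several oligonucleotides, these differed by over 2-fold in 14 of 19 genes at 4 h and 24 of 33 at 24 h.

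A gene was called where both arrays of a time lay at least 1 log2 unit, or 2-fold, from 0 on the same side. The number of genes at least 2-fold on both arrays in opposite directions served as the measure of array error. A value ± SD is the mean and SD of the 2 arrays of a time (n = 2 arrays), which covers array and dye error and not the spread between animals. Genes were called between the times where the means differed by at least 1 log2 unit and both arrays of one time lay above both of the other. Lists of genes, 29 in all, were fixed before the data were examined, and covered leukocyte adhesion, coagulation, chemokines, cytokines, the NF-kB and Toll-like receptor pathway, the interferon response, acute-phase proteins, antigen presentation, vasoactive mediators, immediate-early regulators, endothelial identity, angiogenesis, cell cycle, apoptosis, oxidative stress, extracellular matrix, fatty acid use, glycolysis, oxidative phosphorylation, ribosomal proteins, chaperones and markers of 8 other cell types. Each list's median was placed among the medians of 10000 random lists of the same size, unmatched for signal, as a description of these arrays. Chance puts 1.45 of the 29 lists outside the middle 95% at each time.

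The genes named were those of a rule fixed before the data were examined. It took the 10 highest and 10 lowest called genes per time, up to 4 called members per list and time with the largest mean, and the 5 largest differences between the times in each direction. Of these, 1700128F08Rik was left out as a clone name. Genes outside the rule were chosen after their values were seen. Cxcl12, Irf2, Oasl2, Cav1, Btg2, Ndufv2, Pgam1, Pgk1, Rpl24, Rpl32 and Pdk4 were named because a count of 5 or fewer held them, and Psmd8 was singled out from the 6 higher proteasome genes.

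The calls were tested on simulated data, in which the real values of each array were shuffled among 11138 genes and 200 genes were shifted by known folds. At 4 h, 20.0% of the genes shifted 2-fold, 86.0% shifted 4-fold and 98.0% shifted 16-fold were called, and at 24 h 30.0%, 66.0% and 98.0%. For 24 h against 4 h the shares were 40.0%, 84.0% and 100%. Alternatives were the centring, scale and quantile normalization, other folds, the pair mean alone, limma 3.58.1 on the arrays as separate samples with Benjamini-Hochberg adjustment, unnamed oligonucleotides, and leaving out each array. Added after the data were seen were ratios of exactly 1 as missing, a 2-fold difference of every spot, and a 2-fold gap between all arrays of the times. Spots were not centred for the second of these, so only 398 of its 401 genes at 24 h were also called by the main criterion. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and R 4.3.3 were used.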

Results

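Gene expression was compared between cardiac endothelium, the cells lining the vessels of the heart, of mice given intraperitoneal LPS and of mice given saline. LPS is a component of the outer membrane of Gram-negative bacteria that is sensed by Toll-like receptor 4. RNA was compared at 4 h and at 24 h, with 2 dye-reversed arrays per time counted as 1 replicate, and 11138 genes were measured on all 4 arrays. The log2 ratios of spots had an SD of 1.59 and 0.98 on the arrays of 4 h and of 1.44 and 1.44 on those of 24 h. Values are log2 LPS over saline, a direction that is likely from the dyes in the labels but not stated in the deposited table. The rule fixed beforehand left it open. With the sign of all arrays turned, every higher would read lower. If the table was already turned alike, called genes would instead lie in opposite directions on the 2 arrays, as under a dye effect. The ± gives the SD of the 2 arrays (n = 2 arrays), and genes called higher or lower were at least 2-fold on both.

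The first comparison asked which genes differed between LPS and saline at 4 h. Interferon-induced genes were the most strongly shifted group, with 18 of 32 measured members higher and 0 lower. Gbp2, a guanylate-binding GTPase, stood at 4.67 ± 0.74, the immunity-related GTPases Ifi47 and Irgm2 at 4.30 ± 0.83 and 2.99 ± 1.25, and Ifit2 at 3.92 ± 0.13. Of 30 chemokine genes, 6 were higher, led by Ccl2, which attracts monocytes, at 4.05 ± 0.28, and by the neutrophil attractants Cxcl1 at 3.84 ± 0.46 and Cxcl2 at 3.74 ± 0.29. Cxcl10, a ligand of the chemokine receptor CXCR3, was at 2.37 ± 0.04, and Cxcl12 was lower at -1.81 ± 0.44. In the NF-kB and Toll-like receptor list, 6 of 28 members were higher, among them Tlr2, a receptor of bacterial lipoproteins, at 3.86 ± 0.21, Tnip1, a partner of A20, at 2.69 ± 0.51, and Tlr3 at 2.13 ± 0.70. Birc3, an inhibitor of apoptosis, was at 2.19 ± 1.47.

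Over all genes, 362 were called at 4 h, 251 higher and 111 lower, against 158 that were 2-fold in opposite directions on the 2 arrays. With shuffled arrays, 139 unchanged genes were called. Quantile normalization called 561 genes, 328 higher and 233 lower, which lowered the share of higher calls. Where every spot of a gene had to be 2-fold, 176 genes were called, 139 higher and 37 lower, against 19 in opposite directions. The sign of replicate 2 was turned on the same kind of spots, so this contrast is no independent measure of error. Of the 68 calls of 4 h named by the preset rule, 16 were not 2-fold in every spot. They were Abtb1, Asf1b, Birc3, Cycs, Dct, Fbxo9, Foxd3, Gadd45g, Hadhb, Kdr, Nudt17, Ptgir, Pycard, Sdhb, Spry2 and Timp1, and Rpl24, named outside the rule, did not either. As separate samples in limma, the arrays gave 0 genes at an adjusted p under 0.05. At an unadjusted p under 0.05 there were 475 genes, where evenly spread p-values give 557. In the simulated data, limma put only 1.75% of unchanged genes under 0.05 at 4 h, so 557 may overstate what chance gives.

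Acute-phase and antimicrobial genes included 4 higher members of 20 at 4 h. Lcn2, which binds bacterial siderophores, was at 4.45 ± 0.90, the metallothionein Mt2 at 4.20 ± 2.16, ceruloplasmin (Cp) at 1.83 ± 0.50 and the LPS-binding protein Lbp at 1.64 ± 0.10. Mt2 was also the 1 called member of 31 in the oxidative stress list. Of 21 antigen presentation genes, 3 class I genes were higher, H2-Q7 at 3.01 ± 0.43, H2-K1 at 2.79 ± 0.46 and H2-D1 at 2.78 ± 0.76. Among 39 immediate-early and stress regulators, 6 were higher and 1 lower. The transcription factor Cebpd stood at 3.51 ± 0.07, Myc at 2.50 ± 1.03 and Ier3 at 1.76 ± 0.50, and the glucocorticoid-induced Tsc22d3 was lower at -1.69 ± 0.57. In the apoptosis list, Casp4, the caspase that binds intracellular LPS, was at 3.91 ± 0.15 and it and Birc3 were the 2 called members of 30. Outside the lists, Gbp8 was at 4.29 ± 0.08 and Ly6f at 4.29 ± 0.54.

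Vascular genes went both ways at 4 h. In the angiogenesis list 4 of 36 members were higher and 1 was lower. Hif1a, a subunit of the hypoxia-inducible factor, stood at 3.75 ± 0.02, the growth factors Pgf and Pdgfa at 3.11 ± 0.80 and 1.86 ± 0.48 and Id3 at 1.46 ± 0.40, while the VEGF co-receptor Nrp1 was at -2.58 ± 0.55. Of 25 endothelial identity genes, the tight junction gene Cldn5 was higher at 1.29 ± 0.10. The VEGF receptor Kdr at -1.89 ± 0.75 and the TGF-beta co-receptor Eng at -1.87 ± 0.84 were lower. The netrin receptor Unc5b at -2.79 ± 0.23, Myct1 at -3.19 ± 0.85 and Tspan17 at -2.81 ± 0.48 were also among the 10 lowest. The other named low genes rested on arrays that differed widely, with Spry2 at -3.41 ± 2.23, Magee1 at -3.36 ± 2.70, Dct at -3.35 ± 3.26, Pycard at -3.15 ± 2.17, Samd8 at -2.90 ± 1.97, Abtb1 at -2.82 ± 2.55 and Nudt17 at -2.77 ± 1.61. Among 28 vasoactive genes, Gch1, which makes the cofactor of nitric oxide synthases, was higher at 2.20 ± 0.61. The receptors Calcrl at -1.91 ± 0.18 and Ptgir at -1.06 ± 0.06 were lower. The adhesion molecule E-selectin (Sele) was the 1 called member of 15 adhesion genes, at 1.43 ± 0.11, and Vcam1 at 1.39 ± 0.84 was not called.

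Metabolic and housekeeping groups also held called genes at 4 h. For scale, 362 of all 11138 genes were called, and shuffled arrays called 139 unchanged genes. The counts of called members in these and the other lists were not tested against this share. Of 53 cytosolic ribosomal protein genes, 11 were higher and 1, Rpl24 at -1.94 ± 0.21, was lower. Rps10 stood at 2.28 ± 0.23, Rps14 at 2.24 ± 0.13, Rplp0 at 2.03 ± 0.36 and Rpl19 at 1.95 ± 0.51. The glycolytic enzymes Ldha at 2.06 ± 0.04 and Aldoa at 1.55 ± 0.44 were the 2 called members of 21, and the chaperones Hspa1b at 1.86 ± 0.28 and Hspb1 at 1.71 ± 0.24 the 2 of 29. Sdhb at 2.03 ± 1.40 and Cycs at 1.96 ± 0.71 were called among 36 oxidative phosphorylation genes, Hadhb at 1.77 ± 0.73 among 26 fatty acid genes and Timp1 at 1.90 ± 0.29 among 34 matrix genes. The cytokine receptor Osmr, at 2.02 ± 0.52, was the 1 called member of 30 cytokine and receptor genes. None of the 15 coagulation or 36 cell cycle genes was called. Among markers of other cells, 0 of 32 cardiomyocyte, 18 neutrophil, 28 monocyte and macrophage, 23 lymphocyte, 9 erythrocyte, 10 platelet and 19 fibroblast genes were called, and 1 of 18 smooth muscle and pericyte genes, Actg2 at 2.18 ± 0.58.

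**Figure D1:**
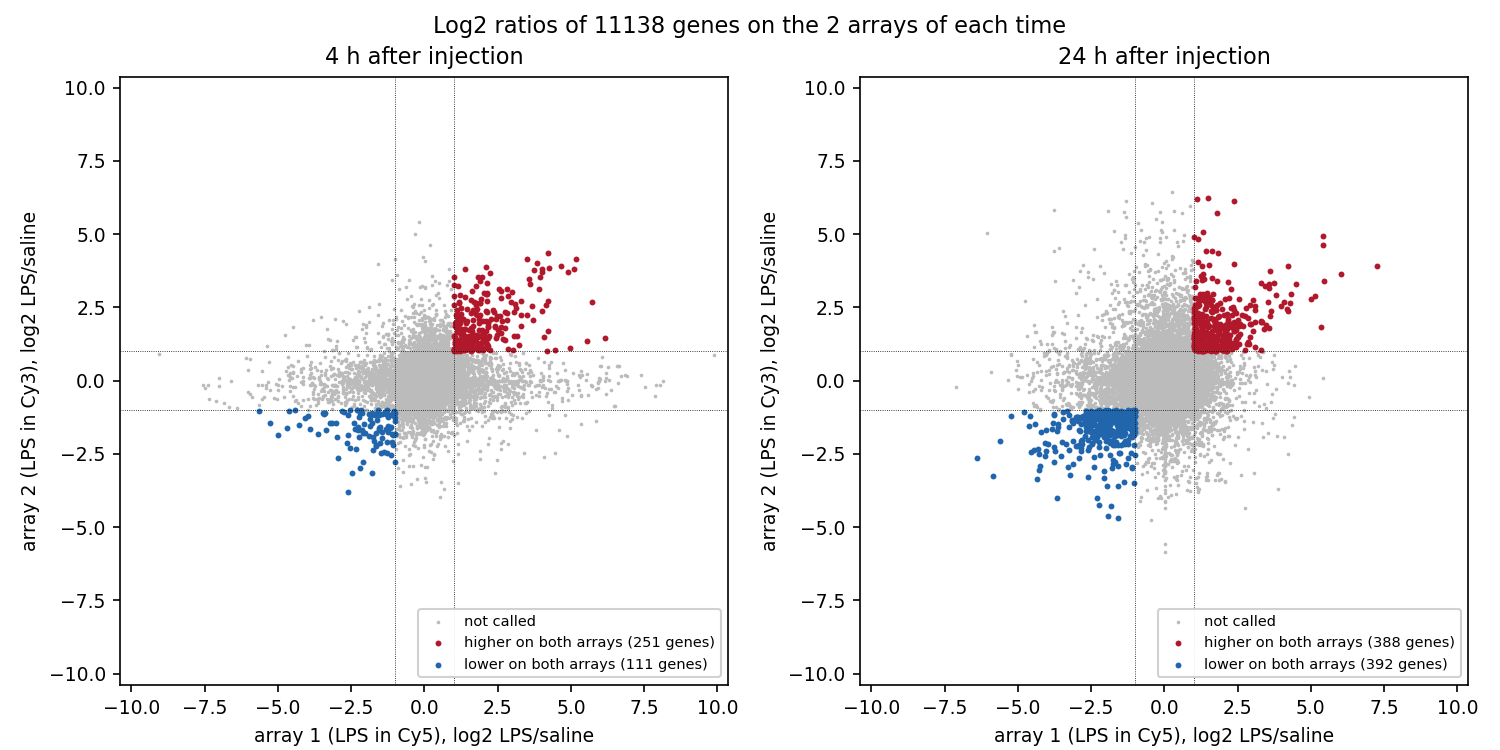
Each point is 1 of 11138 genes, with the log2 LPS over saline of array 1 (LPS in Cy5) on the x axis and of array 2 (LPS in Cy3) on the y axis, at 4 h on the left and 24 h on the right. Dotted lines mark 2-fold, and called genes are coloured, 251 higher and 111 lower at 4 h and 388 higher and 392 lower at 24 h.

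The same question was asked at 24 h. Interferon-induced genes were again higher, 11 of 32, with Gbp2 at 5.01 ± 0.56, Ifi47 at 3.65 ± 0.95, Tgtp1 at 3.37 ± 0.29 and Irgm2 at 2.41 ± 0.03, and Irf2 at -1.72 ± 0.41 and Oasl2 at -1.47 ± 0.56 were lower. Lcn2, at 5.17 ± 0.34, was the highest called gene after Rps29. Endothelial identity genes were higher in 5 of 25 cases. Gpihbp1, which anchors lipoprotein lipase on capillaries, stood at 4.06 ± 0.21, Eng at 3.91 ± 0.85, the fatty acid transporter Cd36 at 3.46 ± 1.15, Kdr at 2.21 ± 0.48 and Cav1 at 1.15 ± 0.19. Lipoprotein lipase itself (Lpl) was at 3.91 ± 1.58, and with Cd36, Pparg at 1.65 ± 0.56, Cpt2 at 1.37 ± 0.45 and Pdk4 at 1.29 ± 0.07 it made up the 5 higher members of 26 fatty acid genes. Only 2 of 30 chemokine genes were called, Ccl2 at 1.73 ± 0.82 and Cxcl1 at 1.49 ± 0.14.

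At 24 h 780 genes were called, 388 higher and 392 lower, against 411 in opposite directions on the 2 arrays and 476 unchanged genes called with shuffled arrays. With scale normalization 424 were called. Where every spot had to be 2-fold, 401 genes were called, 214 higher and 187 lower, against 62 in opposite directions. As at 4 h, this contrast is not independent of the turned sign. Of the 101 calls of 24 h named by the rule, 24 were not 2-fold in every spot. They were Actg2, Asf1b, Bag3, Casp12, Cpt2, Cycs, Dll4, Fpr2, Fstl1, H2-D1, Il18bp, Klf1, Mgp, Ngdn, Ngp, Nos1, Osmr, Pkm, Prdx1, Psmb10, Ryr2, Saa3, Slc7a11 and Vcam1, and Cav1, Ndufv2, Oasl2, Pgam1 and Rpl32, named outside the rule, did not either. A small SD of the arrays did not mean that spots agreed, as those of Nos1 ran from -3.82 to 0.29 and those of Ryr2 from -3.93 to 0.42. limma gave 0 genes at an adjusted p under 0.05, with 1126 genes at an unadjusted p under 0.05. Evenly spread p-values give 557, and in the simulated data limma put 5.60% of unchanged genes under 0.05 at 24 h.

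Ribosomal protein genes were higher in 13 of 53 cases at 24 h, and Rpl32 at -1.86 ± 1.14 was lower. Rps29 stood at 5.59 ± 2.38, Rpl13a at 4.83 ± 1.67, Rpl27 at 4.42 ± 1.46 and Rps23 at 3.42 ± 0.20. At 4 h these genes were not called, at 0.08, -0.05, 0.04 and 0.32. In turn Rps10, Rps14, Rplp0 and Rpl19, named as higher at 4 h, were not called at 24 h. The ribosomal genes named as higher thus differed between the times. Oxidative phosphorylation genes were higher in 4 of 36 cases, Atp5h at 2.06 ± 1.15, Ndufb5 at 1.89 ± 0.20, Ndufa2 at 1.72 ± 0.39 and Cycs at 1.70 ± 0.28, and Ndufv2 at -1.23 ± 0.11 was lower. Of 21 glycolysis genes 5 were higher, Pfkfb3, an activator of glycolytic flux, at 2.75 ± 0.24, Pkm at 1.49 ± 0.25, Eno3 at 1.37 ± 0.26, Pgam1 at 1.15 ± 0.16 and Pgk1 at 1.09 ± 0.03. Ldhb was lower at -1.95 ± 0.65. Of 31 oxidative stress genes, Mt2 at 3.66 ± 0.09 and the peroxiredoxins Prdx1 at 1.73 ± 0.47 and Prdx2 at 1.19 ± 0.18 were higher, and Slc7a11 at -1.46 ± 0.50 was lower. Of 29 chaperone genes, the endoplasmic reticulum chaperones Hspa5 at 1.74 ± 0.66 and Hsp90b1 at 1.40 ± 0.48 were higher. The cytosolic co-chaperones Dnajb1 at -3.10 ± 1.36 and Bag3 at -1.31 ± 0.16 were lower. The small GTPase Rhoc at 4.01 ± 1.59 and Acyp2 at 4.27 ± 2.65 were among the 10 highest genes.

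Inflammatory and vascular regulators were mixed at 24 h. Of 20 acute-phase genes 5 were higher, with Cp at 2.70 ± 0.61, Saa3 at 2.35 ± 0.94 and Lbp at 1.91 ± 0.92 beside Lcn2 and Mt2. Lbp, Tnip1 at 1.87 ± 0.22 and Tlr2 at 1.73 ± 0.78 were the 3 higher members of the NF-kB and Toll-like receptor list of 28. Tnfaip3 (A20), an inhibitor of NF-kB, was lower at -1.80 ± 0.36. Of 28 vasoactive genes, inducible nitric oxide synthase (Nos2) at -3.50 ± 1.49, arginase 1 (Arg1) at -3.22 ± 0.02 and Nos1 at -1.80 ± 0.05 were lower, and Calcrl at 1.30 ± 0.33 and Cav1 were higher. Of 15 coagulation genes, Anxa2, which binds plasminogen, at 2.75 ± 0.50 and Serping1 at 2.50 ± 0.52 were higher, and the anticoagulant receptor thrombomodulin (Thbd) was lower at -1.64 ± 0.69. Timp3 at 3.30 ± 1.29 and the basement membrane chains Col4a1 at 1.95 ± 0.26 and Col4a2 at 1.53 ± 0.12 were higher among 34 matrix genes, and Col18a1 was lower at -2.29 ± 0.82. Of 39 immediate-early and stress regulators, Ier3 at 3.59 ± 2.48, Tsc22d3 at 2.28 ± 0.05, Gadd45g at 1.81 ± 0.75 and Klf4 at 1.51 ± 0.64 were higher, and Btg2 was lower at -1.28 ± 0.24.

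The remaining lists also held called genes at 24 h. For scale, 780 of all 11138 genes were called, and shuffled arrays called 476 unchanged genes. The counts of called members in these and the other lists were not tested against this share. Of 15 adhesion genes, Vcam1 was higher at 1.33 ± 0.41 and Itga5 lower at -1.30 ± 0.07. Of 30 cytokine and receptor genes, Osmr at 1.47 ± 0.23 and Il18bp at 1.40 ± 0.53 were higher and Ltb at -2.02 ± 0.79 was lower. Psmb10 at 2.66 ± 0.88 and H2-D1 at 1.52 ± 0.69 were called among 21 antigen presentation genes. Casp4 at 2.27 ± 0.47, Casp1 at 1.42 ± 0.16, Bad at 1.23 ± 0.01 and Casp12 at 1.09 ± 0.12 were called among 30 apoptosis genes. Hif1a at 2.37 ± 0.10 and Id3 at 1.75 ± 0.73 were higher and Dll4 at -1.30 ± 0.13 was lower among 36 angiogenesis genes, and Kif11 at 1.98 ± 0.51 was the 1 called cell cycle gene of 36. Among markers of other cells, the neutrophil genes S100a8 at 2.58 ± 1.17, S100a9 at 1.55 ± 0.08 and Fpr2 at 1.20 ± 0.08 were higher and Ngp at -1.62 ± 0.82 was lower. Coro1a at 2.73 ± 1.70 was called among monocyte and macrophage genes, Cd5 at -2.0 ± 1.00 among lymphocyte genes and Ryr2 at -1.40 ± 0.11 among cardiomyocyte genes. Klf1 at 2.01 ± 0.24 and Car1 at -1.75 ± 0.11 were called among erythrocyte genes. Vim at 2.04 ± 0.48, Mgp at 1.80 ± 0.91 and Fstl1 at 1.32 ± 0.20 were called among fibroblast genes, and Actg2 at -2.42 ± 1.47 among smooth muscle genes. No platelet gene was called. The lowest genes of 24 h were, beside Nos2, the neurotrophin receptor Ntrk3 at -4.54 ± 1.83, Flacc1 at -4.51 ± 2.65, Reg4 at -3.85 ± 0.71, the embryonic signal Nodal at -3.84 ± 2.51, the neuronal sodium channel Scn2a at -3.82 ± 0.24, Nfatc2 at -3.66 ± 0.86, Sox13 at -3.57 ± 0.95, Foxd3 at -3.40 ± 1.47 and Usp26 at -3.39 ± 1.27.

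**Figure D2:**
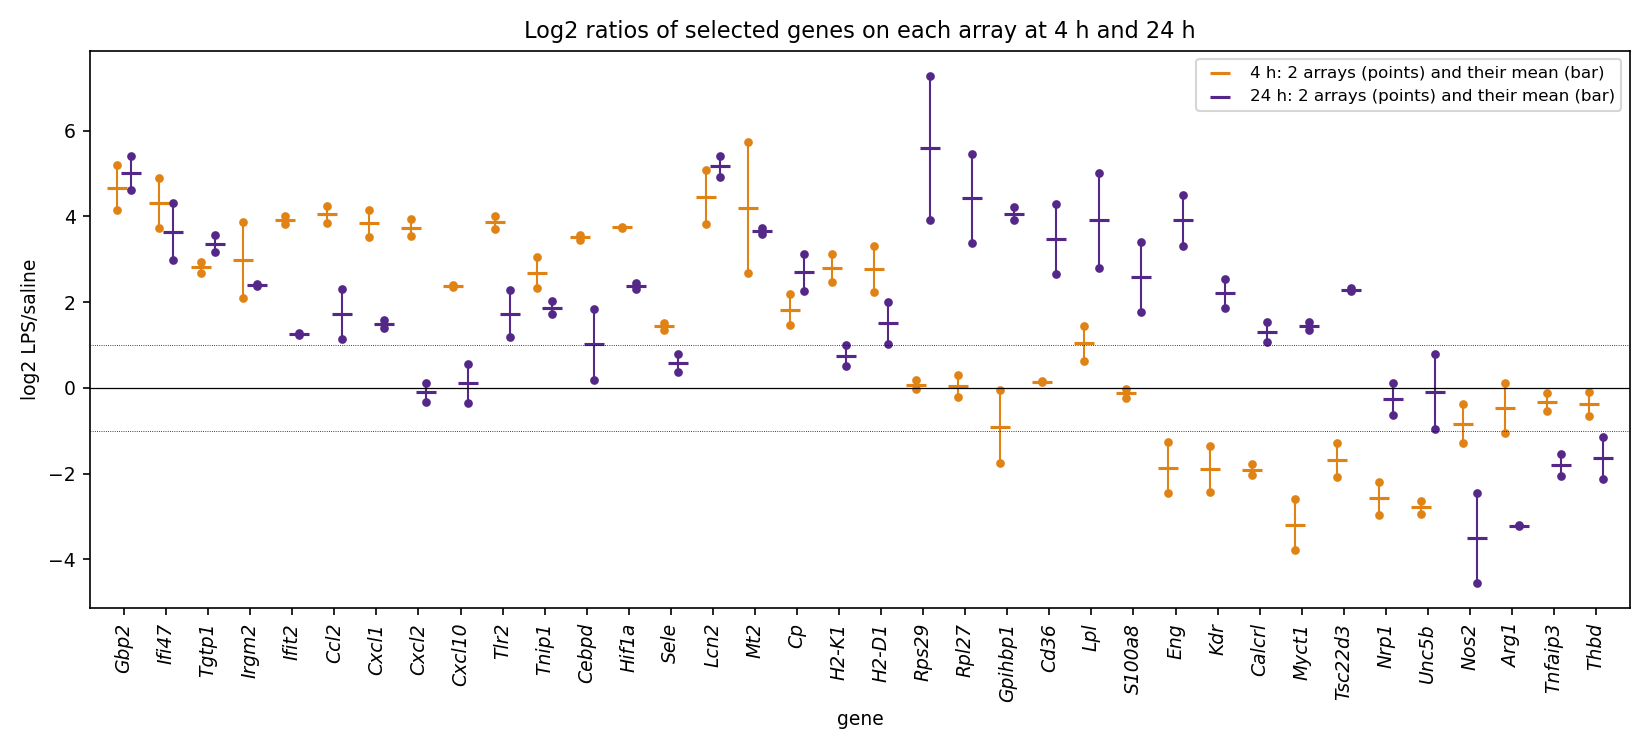
Log2 LPS over saline of 36 genes on the y axis, with 4 h in orange and 24 h in purple, where points are the 2 arrays of a time, the horizontal bar is their mean and dotted lines mark 2-fold. Cxcl2 and Cxcl10 lie above 2-fold at 4 h and near 0 at 24 h, and Eng, Kdr, Calcrl, Myct1 and Tsc22d3 are over 2-fold lower at 4 h and over 2-fold higher at 24 h on both arrays.

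The medians of whole lists were set against random lists. At 4 h, 8 of the 29 lists had a median outside the middle 95% of random lists, all of them above it. The interferon response had a median of 1.74, ribosomal proteins 0.62, the NF-kB and Toll-like receptor pathway 0.53, coagulation 0.36, antigen presentation 0.26, chemokines 0.24, apoptosis 0.23 and immediate-early regulators 0.19. On each array alone, the interferon, ribosomal and NF-kB lists stayed above the middle 95%, and the chemokine, coagulation, antigen presentation, apoptosis and immediate-early lists did so on 1 array. Medians on the first and second array were 1.20 and 2.30 for interferon, 0.76 and 0.12 for ribosomal and 0.26 and 0.59 for NF-kB genes. For coagulation they were 0.05 and 0.30. At 24 h, 7 lists lay above the middle 95%. These were the interferon response at 0.71, ribosomal proteins at 0.63, leukocyte adhesion at 0.48, endothelial identity at 0.43, extracellular matrix at 0.42, antigen presentation at 0.38 and oxidative phosphorylation at 0.34. The interferon, ribosomal and endothelial lists stayed so on each array alone, and the other lists did not. None of the 8 lists of other cell types lay outside the middle 95% at 4 h or at 24 h. The random lists were drawn from all genes and not matched for signal. Ratios that depend on signal could therefore also raise a list, which could not be tested without intensities.

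**Figure D3:**
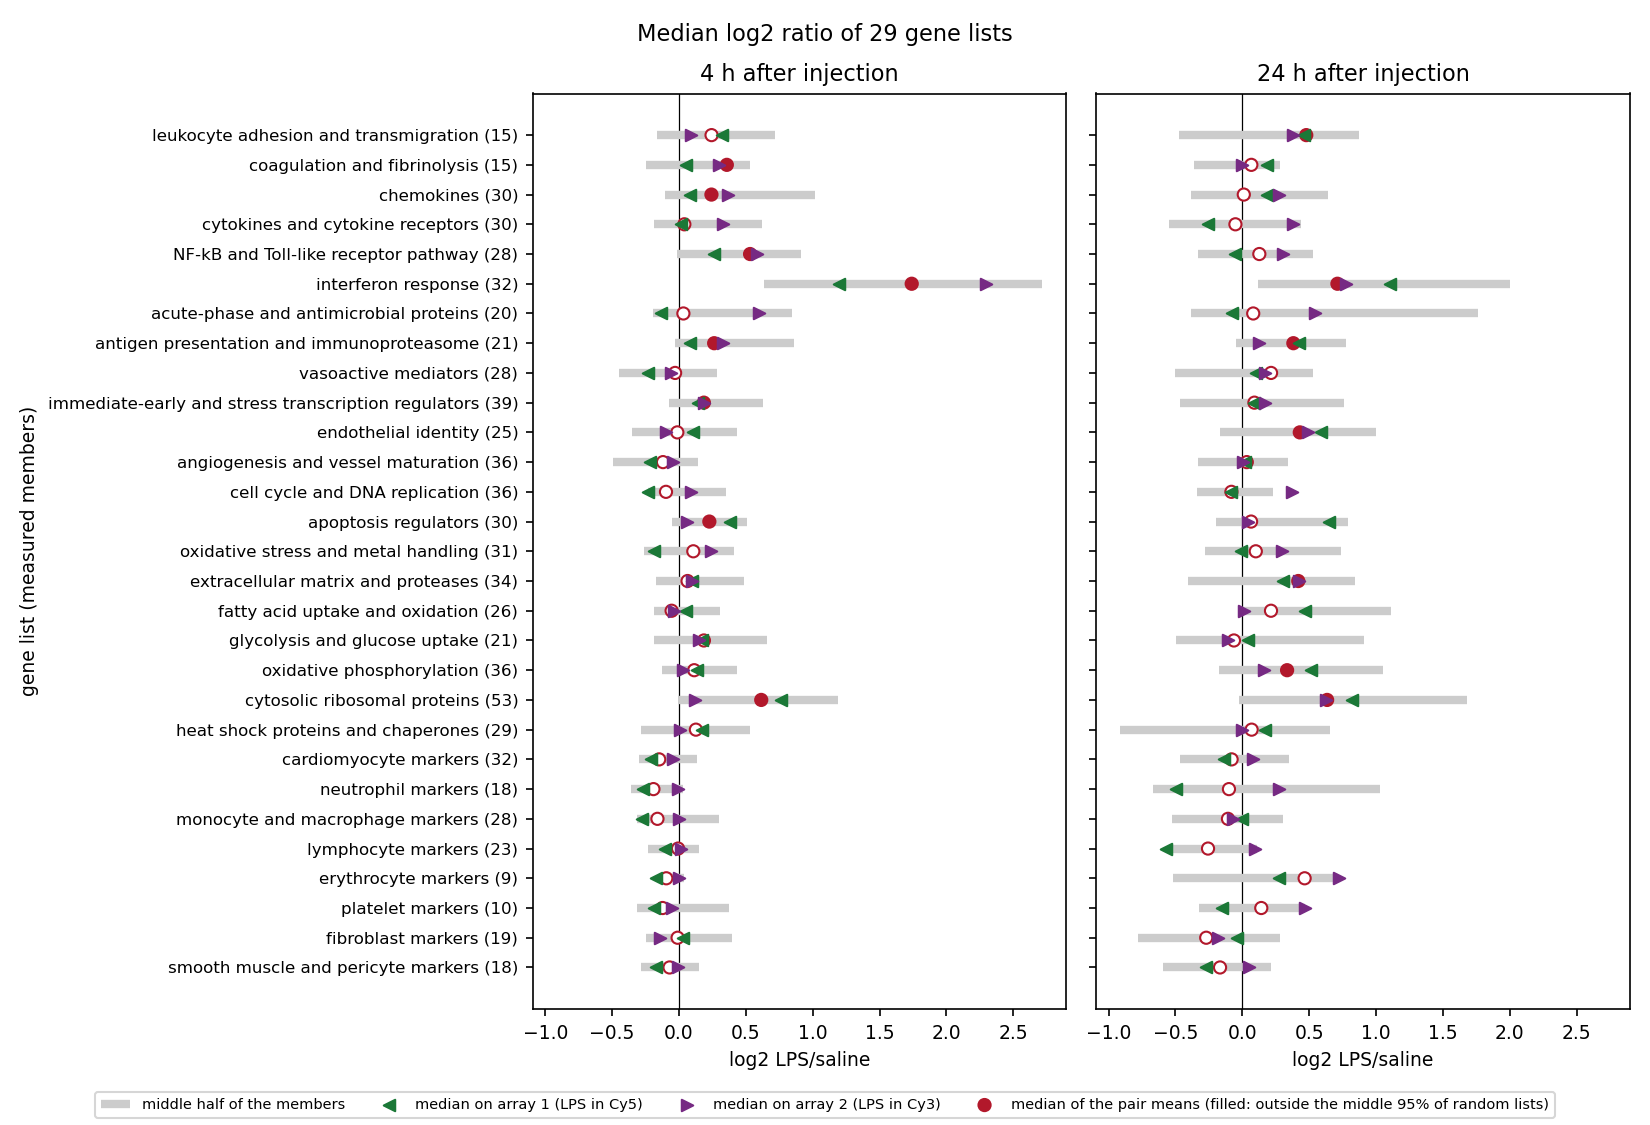
Median log2 LPS over saline (x axis) of 29 gene lists (y axis, measured members in brackets) at 4 h on the left and 24 h on the right, where circles are medians of the pair means, triangles the medians on each array and grey bars run from the lower to the upper quartile of the members. Filled circles lie outside the middle 95% of 10000 random lists, and the interferon response lies furthest from 0 at 4 h, at 1.74, and at 24 h, at 0.71.

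The next comparison set 24 h against 4 h. Among genes higher at 24 h, Eng differed by 5.77, Rps29 by 5.52 and Fbxo9 by 5.27. Trmt5 and Dpysl5 differed by 5.77 and 5.39. Fbxo9 at 3.87 ± 3.35 and Rps29 at 24 h, and Trmt5 at -3.86 ± 5.25 and Dpysl5 at -3.67 ± 3.87 at 4 h, rested on arrays far apart. Among genes lower at 24 h, Asf1b differed by -5.77, Ly6f by -5.21, Ngdn by -4.71 and Actg2 by -4.60, with arrays far apart for Asf1b at 3.46 ± 2.97 and Ngdn at 3.53 ± 4.70 at 4 h. The chemokine genes Cxcl2 and Cxcl10 differed by -3.84 and -2.27, and Gpihbp1 and Cd36 by 4.97 and 3.32. By the criterion of separated arrays, 2201 genes differed, 1050 higher and 1151 lower at 24 h. Crossing dye and time gave 1185 genes, splitting the same 4 arrays by dye, which also holds dye effects of genes, gave 2267, and shuffled arrays gave 2019 of 10938 unchanged genes. The count for time was thus above the crossed split and below the split by dye. Both arrays of one time lay above both of the other in 37.5% of genes, where chance gives 33.3%. Whether the count for time exceeds array error was not tested. With a 2-fold gap between all arrays of the times, 615 genes differed, against 536 by dye and 224 crossed. Between the times limma gave 0 genes at an adjusted p under 0.05. At an unadjusted p under 0.05 it gave 638, where evenly spread p-values give 557.

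The last comparison asked how far the 2 times agreed. Of the genes called at both times, 54 were higher at both, where independent lists would share 8.74. They included Gbp2, Ifi47, Ifit2, Irgm2, Tgtp1, Ccl2, Cxcl1, Lcn2, Mt2, Tlr2, Tnip1, Casp4 and Hif1a. Only 3 genes were lower at both times, against 3.91 for independent lists. A further 15 were lower at 4 h and higher at 24 h, against 3.87, among them Eng, Kdr, Calcrl, Myct1, Tsc22d3 and Fbxo9. Higher at 4 h and lower at 24 h were 4 genes, Actg2 and Asf1b among them, against 8.83. All 76 genes called at both times, taken with the directions at each time, would give 52.7 higher at both and 16.3 lower at 4 h and higher at 24 h. Where every spot had to be 2-fold, 35 genes were higher at both times, against 2.67 for independent lists, and 1 was lower at both, against 0.621. The 15 genes lower at 4 h and higher at 24 h became 6, without Kdr and Fbxo9, against 0.711, and 1 was higher at 4 h and lower at 24 h, against 2.33. Across all 11138 genes, which are not independent replicates, the pair means of the 2 times correlated at r = 0.079 and rho = 0.068. Between arrays of opposite dyes, it was -0.079 for the first of 4 h and the second of 24 h, and 0.027 for the other pair. Between arrays of the same dye, it was 0.171 with LPS in Cy5 and 0.056 with LPS in Cy3. If the 2 times shared saline RNA, part of the overlap may come from it, which the labels leave open.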

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

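All tests in this part were chosen after the values were seen. Genes called in opposite directions at 4 h and 24 h numbered 19, a number that was not tested. By the definition of a call, each had both arrays of one time on one side and both of the other time on the other side. Between the times, limma on the arrays as separate samples gave 0 genes at an adjusted p under 0.05 (smallest 0.804). Among the named genes, 24 h minus 4 h was 5.77 for Eng, 4.10 for Kdr, 3.20 for Calcrl, 4.63 for Myct1, 3.97 for Tsc22d3 and 5.27 for Fbxo9. It was -4.60 for Actg2 and -5.77 for Asf1b.

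Of these genes, 15 were lower at 4 h and higher at 24 h, and they included the endothelial receptors Eng, Kdr and Calcrl, of which Kdr was not 2-fold in every spot at 4 h. Whether probes that vary more than others, and so are called at both times, explain this stays open. The directions at each time among the 76 genes called at both times would give 16.3 such genes. The 15 genes themselves enter that number, so it cannot decide. A larger endothelial share in the LPS isolate at 24 h stays open too. The endothelial identity list had a median of 0.43 (99.5th percentile of random lists), and its 23 genes outside the pattern had a median of 0.30, at the 96.9th percentile, with a middle range of -0.29 to 0.87. A time-dependent response of these genes to LPS, lower first and higher later, stays open as an untested hypothesis, as does a difference between the saline samples of the 2 times.

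Oligonucleotides with no single gene symbol stood outside the main comparisons and entered only an alternative. Of 4052, 148 were at least 2-fold in the same direction on both arrays at 4 h, against 117 in opposite directions, and 201 at 24 h, against 172. Whether these exceed array error was not tested.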

How the results depend on the processing

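Alternatives for ratios of exactly 1, every spot and the gap between all arrays of the times were chosen after the data were seen. At 4 h, against 362 genes, scale normalization called 557, quantile normalization 561, the pair mean alone 1403, 1.5-fold 941, 3-fold 126, all oligonucleotides 559, every spot 176 and limma 0, with and without a dye term. Calls on a single array numbered 1414 without the first and 2317 without the second. At 24 h, against 780 genes, scale normalization called 424, the pair mean alone 2291, 1.5-fold 1808, 3-fold 235, every spot 401, limma 0 with and without a dye term, and a single array 3239 without the first and 3408 without the second. With the dye term, 721 genes at 4 h, 1240 at 24 h and 813 between the times had an unadjusted p under 0.05. In the simulations for 4 h and 24 h, with changes of up to 16-fold, limma also called 0 genes. Between the times, against 2201 genes, limma gave 0, a gap between all arrays 615, and leaving out an array 2968 (first of 4 h), 3595 (second of 4 h), 4001 (first of 24 h) and 3756 (second of 24 h). The correlation between the times of 0.079 turned to -0.079 between the first array of 4 h and the second of 24 h. It was 0.027 for the other pair of opposite dyes and 0.211 over genes called at either time. When an array was left out, it ranged from -0.036, without the first array of 24 h, to 0.152. The lists outside the middle 95% at 4 h, 8 in all, numbered 5 without the second array, 4 above and 1 (monocyte and macrophage markers) below, and 10 without the first. At 24 h, without the second array, 6 lay above and 1 (lymphocyte markers) below, where all arrays put 7 above and 0 below. Stricter or looser folds, more features and fewer arrays change counts by construction, and for the other settings the cause was not tested. List medians were counted once per list, time and setting. Of those under settings that kept all arrays, 248 moved by less than their spread and 42 by more. Of the 116 with an array left out, 83 moved by less and 33 by more. Values of named genes were counted once per gene, time of a call and setting. Of these values, 305 moved by less than their spread and 33 by more without centring or with quantile normalization, 32 of the 33 with the latter. Leaving out an array of a pair cannot move a called gene beyond the SD of the pair or turn its sign, so it was not counted for genes. The setting that required values on all 4 arrays removed no gene, and its signal filter was not run because the table used here holds no signals, so how far weak signal limits these ratios is unknown.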

Other observations

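All tests in this part were chosen after the values were seen. Gene families named by their symbols were tested beside the fixed lists. Of 38 proteasome subunit genes, which form the complex that degrades ubiquitinated proteins, 6 were higher at 24 h and 0 lower, with Psmd8 at 3.37 ± 0.64 and the immunoproteasome subunit Psmb10, also in the antigen presentation list, at 2.66 ± 0.88 (SD, n = 2 arrays). This was 15.8% of the family against 3.44% of other genes (2-sided Fisher's exact test across genes, p = 0.00184, adjusted p = 0.0256 over 20 tests). The family median was 0.68 at 24 h and 0.29 at 4 h, and it was above 0 under scale and quantile normalization and without centring. At 4 h 4 members were higher (adjusted p = 0.0679). Genes are not independent replicates, so these p-values describe these arrays. Mitochondrial ribosomal proteins (66 genes), keratins (69 genes) and homeobox cluster genes (32 genes) had no adjusted p under 0.05. The mitochondrial ribosomal proteins still had a median of 0.29 at 24 h (99.95th percentile of random lists), with 0.38 and 0.24 on the 2 arrays. A raised median at 24 h was thus not particular to the proteasome.

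For the 392 genes lower at 24 h, array error stays open. If the sign of replicate 2 was turned rightly, a gene's dye effect falls in opposite directions on the 2 arrays. It then cannot by itself give a lower call. Every spot was 2-fold lower for 187 genes, 186 of them among the 392, against 62 in opposite directions on the 2 arrays. These counts cannot decide, since the sign was turned on the same kind of spots. Ratios that depend on signal, with unused probes reading low, remain a candidate explanation, as of 116 odorant, vomeronasal and taste receptor genes, best known from sensory neurons, 11 were lower, 9.48% against 3.46% of other genes (one-sided Fisher's exact test, p = 0.00255, 2-sided adjusted p = 0.0256 over the 20 tests). Their median was 0.02 on the first array and -0.51 on the second, and 5 were lower after quantile normalization, 4.31% against 2.24% (same exact test, p = 0.123), 5 after scale normalization, against 1.88% (p = 0.0705), and 9 without centring, against 3.15% (p = 0.0120). At 4 h they went the other way, with 0 lower against 1.01% of other genes and a median of 0.08 (98.5th percentile of random lists). A lower level of these genes under LPS stays open as a hypothesis.

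S100a8 and S100a9, abundant in neutrophils, were higher at 24 h at 2.58 ± 1.17 and 1.55 ± 0.08. Neutrophil RNA in the isolate may account for this, but the median of the 16 other neutrophil markers was -0.15, at the 23.9th percentile of random lists, with a middle range of -0.73 to 0.34. This neither shows nor excludes a small share of neutrophils, since the table holds no intensities to tell which markers were above background. Higher expression by the endothelium itself and neutrophil RNA cannot be told apart here.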
